A study of Homo sapiens with 6 samples.

How the data were processed

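Total RNA from MEC-1 cells was labelled with biotin using a whole-transcript kit and hybridised to 1 Affymetrix array per sample, per the labels, with 3 arrays from UGT2B17 knockdown cells and 3 from scrambled shRNA cells. The deposited values are on a log2 scale and, per the submitters' processing notes, were made with RMA, a method that corrects background, normalises between arrays by quantiles and summarises probes into probe sets. Its version and the library files behind the probe sets are not given in the sources used here. The deposited values, from 2.20 to 14.3 on 32321 probe sets, were used without further transformation. RMA compresses fold changes of probe sets near background, and quantile normalisation hides a shift shared by most genes. No batch, slide or scan information was used here, since the sources give none. The number of arrays limits the precision, and groups were taken from the labels.

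Probe sets were named through the platform's annotation, in which 19158 probe sets have 1 gene symbol, 1388 have several and 11775 of the deposited probe sets are not listed and stay unnamed here. Of those with 1 symbol, 19128 matched the RefSeq gene table of assembly GRCh38.p14 by Entrez gene identifier, and 0 symbols needed an update. The build behind the array annotation is not given in the sources used here, so no coordinates are printed and the table served only for names and gene order. Probe sets naming several genes were left out of the gene test, and those naming UGT2B17 are reported by probe set. For the 637 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was kept, which left 18404 genes. No filter on dim probe sets was applied. For ELL2 the other probe set gave −0.56 log2 units against −0.51, for NHP2 the dimmer one gave −0.18 against −0.28, and for KRT18 the dimmer one gave 0.13 against 0.32. Whether the kept probe sets read the loci of these genes was not tested.

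Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariate), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The moderated variance had 4.82 prior degrees of freedom. Fold changes are knockdown minus scrambled, and SDs are over 3 arrays. The 33 gene lists held 1167 distinct genes, of which 1043 were measured, 42 of them through an older symbol, and 124 were not measured here. They covered drug, steroid, lipid and energy metabolism, B cell, CLL and signalling genes, stress responses, the cell cycle, and markers of T and NK cells, monocytes and granulocytes, erythroid cells and platelets, and epithelial cells and fibroblasts. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists. Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names UGT2B17, the 12 genes with the largest absolute log2 fold change in each direction among those that passed, and up to 4 members of each list with the smallest unadjusted p.

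Alternatives were another quantile normalisation, centring each array on its median, only the brighter genes, an intensity trend or a robust prior in eBayes, array weights, all single-gene or all deposited probe sets, the replicate number as a block, leaving out each array in turn, an adjusted p under 0.1, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. Neither scaling moved the median log2 fold change of all genes, −0.002, by over 0.1. The gene test was tested on simulated data for 18404 genes with 3 against 3 arrays and 200 changed genes per run: it recovered 91.2% of genes changed by 0.5 log2 units with 6.37% false among the calls, and 100% of those changed by 1 with 7.06% false. Both false shares lay above the threshold of 0.05. The simulated genes were independent and the arrays equally variable, unlike the real arrays, whose weights ran from 0.2496 to 6.12. Recovery in the real data may therefore be lower. Camera called a list shifted by 0.3 log2 units in 20 of 20 runs with independent genes, and made 1 call of another list over all runs.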

Results

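Gene expression was measured in MEC-1, an established B cell line derived from chronic lymphocytic leukemia (CLL), after lentiviral delivery of a short hairpin RNA (shRNA). Of 6 arrays, 3 came from cells with an shRNA against UGT2B17, an enzyme that attaches glucuronic acid to androgens and other small molecules, and 3 from cells with a scrambled control shRNA. The arrays carried 32321 probe sets, of which 18404, 1 per gene, entered the comparison. Pearson correlations between pairs of arrays over all probe sets lay between 0.991 and 0.996. Scrambled replicate 3 stood furthest from its own group, with a root mean square deviation of 0.166 log2 units from the group mean against 0.117 to 0.142 for the other arrays. Scrambled replicate 1 correlated slightly more with the knockdown arrays, at a mean r of 0.9946, than with its own group, at 0.9943. The number of arrays, 3 per group, limits the precision of every value. The replicates are described as independent, but the labels do not say that they were separate cultures, so p-values measure only the spread between these arrays.

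The comparison sets cells with the UGT2B17 shRNA against cells with the scrambled shRNA, and the targeted gene comes first. The labels give neither the number of targeting constructs nor separate cultures. For any other gene, effects of lower UGT2B17, of the hairpin on other transcripts and of differences between cultures cannot be told apart. UGT2B17 fell with the knockdown on the probe set annotated to it alone, 8100734, from 3.85 ± 0.14 with scrambled shRNA to 3.21 ± 0.05 log2 units (SD, n = 3 each). The log2 fold change was −0.64 ± 0.08 (SE), with a 95% interval of −0.82 to −0.45, and 64.4% of the scrambled signal was left (limma, adjusted p = 0.00654). This probe set was dim, at percentile 8.02 of all deposited probe sets by mean level, where background compresses fold changes. All 3 knockdown arrays lay below all 3 scrambled arrays, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows.

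Brighter probe sets shared by UGT2B17 and its near-identical relatives were also lower. Probe set 8100746, annotated to UGT2B17 and UGT2B15, read 8.06 ± 0.05 with scrambled shRNA and 6.72 ± 0.15 with the knockdown, a log2 fold change of −1.34 ± 0.09 (SE) or 2.54-fold lower (limma over all probe sets, adjusted p = 0.0137). Probe set 8100758, annotated to UGT2B11, UGT2B17, UGT2B15, UGT2B10 and UGT2B7, read 9.34 ± 0.27 and 7.84 ± 0.19, or 2.84-fold lower (adjusted p = 0.0265). A dim probe set annotated to 7 genes, 8100768, had a log2 fold change of −0.21 ± 0.06 (SE), which did not pass (adjusted p = 0.226). Which of the annotated genes gave the shared signal cannot be read from these probe sets. Of the 21 genes of the UGT enzyme list, 9 were measured on probe sets naming 1 gene. UGT2B11 and UGT2B15 were not among them, so whether the knockdown spared these relatives cannot be read here. Of the 9 measured members, UGT2B17 fell and 8 did not pass over all genes. Adjusted over the list alone, 1 was higher and 1 lower. The list as a whole had a mean log2 fold change of −0.12 ± 0.09 (SE over members) and was not called by camera, limma's competitive gene set test (adjusted p = 0.256).

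**Figure D1:**
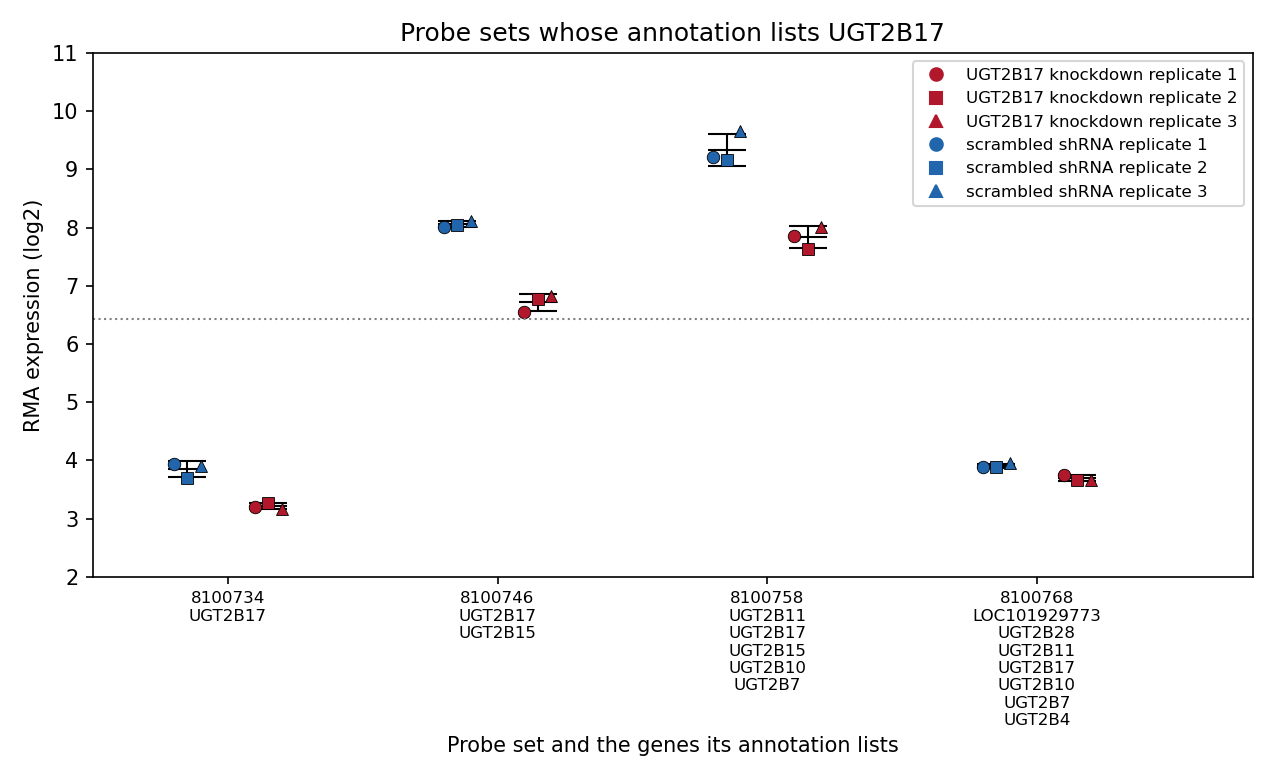
Expression (vertical axis, RMA log2) of the 4 probe sets whose annotation lists UGT2B17 (horizontal axis), with 1 symbol per array, the mean and SD of each group as bars, and the median of all probe sets, 6.43, as the dotted line. Knockdown arrays lie below scrambled arrays on each of the 4, and the gap is widest on the brighter shared sets, at 2.54-fold and 2.84-fold.

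Across the transcriptome, 665 of 18404 genes changed (limma, Benjamini-Hochberg adjusted p under 0.05): 354 were higher and 311 lower in the knockdown. The balance turned with arrays centred on their median, to 275 higher and 316 lower, or 46.5% higher against 53.2%. The median absolute log2 fold change of these genes was 0.44, and 17 reached 1 or more, 9 higher and 8 lower. At an unadjusted p under 0.05 there were 3341 genes, where chance gives 920.2. Each of the 665 genes separated the groups without overlap, as did 24.8% of all tested genes, where chance gives 10%. The gene count was 181, 152 and 175 without knockdown replicates 1, 2 and 3 and 188 without scrambled replicate 2. Of these genes, 177, 150, 173 and 186 were among the 665. Such fits have fewer residual degrees of freedom, which may by itself lower the count, so the drop need not mark any single array. The count did not fall without scrambled replicates 1 and 3, at 694 and 759, despite the same loss of degrees of freedom.

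The strongest increases were in CDH17, a cell adhesion cadherin, and GZMK, the serine protease granzyme K. CDH17 rose by 2.04 ± 0.17 log2 units (SE; 4.13-fold; adjusted p = 0.00119) and GZMK by 2.01 ± 0.19 (4.02-fold; adjusted p = 0.00207). BHLHE41, a transcriptional repressor of the circadian clock, rose by 1.37 ± 0.09, and SCN3A, a voltage-gated sodium channel subunit, by 1.22 ± 0.09. Metabolic genes among the 12 strongest increases were ALDH1L2, a mitochondrial folate enzyme, at 1.18 ± 0.12, SPTSSB, a subunit of serine palmitoyltransferase, at 0.98 ± 0.08, and SLC7A11, the cystine/glutamate exchanger, at 0.98 ± 0.07. Signalling and surface genes were CCL20, a chemokine ligand of CCR6, at 1.12 ± 0.11, GEM, a small GTPase, at 1.11 ± 0.08, CD109, a glycosylphosphatidylinositol-anchored protein, at 1.02 ± 0.14, and FGFR1, a fibroblast growth factor receptor, at 0.98 ± 0.06. GABARAPL1, an autophagy protein of the ATG8 family, rose by 1.08 ± 0.11.

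Among the 12 strongest decreases, CD86, a costimulatory ligand for T cells, fell by 1.33 ± 0.10 log2 units (SE; 2.51-fold lower; adjusted p = 0.000834). CD38, an NAD-consuming surface enzyme used as a prognostic marker in CLL, fell by 1.14 ± 0.08 (2.21-fold lower; adjusted p = 0.000834). DPP4, the surface peptidase CD26, fell by 1.07 ± 0.12, ITGAL, the alpha chain of the integrin LFA-1, by 0.94 ± 0.06, and PTGER2, a prostaglandin E2 receptor, by 0.97 ± 0.16. SLC38A4, an amino acid transporter, fell by 1.24 ± 0.11. CASP1, the inflammasome protease, fell by 1.15 ± 0.10, and GBP6, an interferon-inducible GTPase, fell by 1.07 ± 0.12. GRAMD1B, a sterol transfer protein of the endoplasmic reticulum (ER), fell by 1.15 ± 0.10, and KBTBD8, a substrate adaptor of a ubiquitin ligase, by 1.13 ± 0.17. SNORD116-24, a small nucleolar RNA with many near-identical copies that may share probe signal, fell by 0.96 ± 0.14, and ENTHD1 by 0.94 ± 0.13. Over the 24 genes, adjusted p ran from 0.000826 for FGFR1, BHLHE41, GEM and ITGAL to 0.0155 for PTGER2. The calls of CD109, KBTBD8, PTGER2 and SNORD116-24 were lost when all deposited probe sets were tested (adjusted p 0.05004, 0.0652, 0.0756 and 0.0656). Leaving out knockdown replicate 1 ended the call of KBTBD8, knockdown replicate 2 those of PTGER2 and SNORD116-24, and knockdown replicate 3 that of PTGER2.

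**Figure D2:**
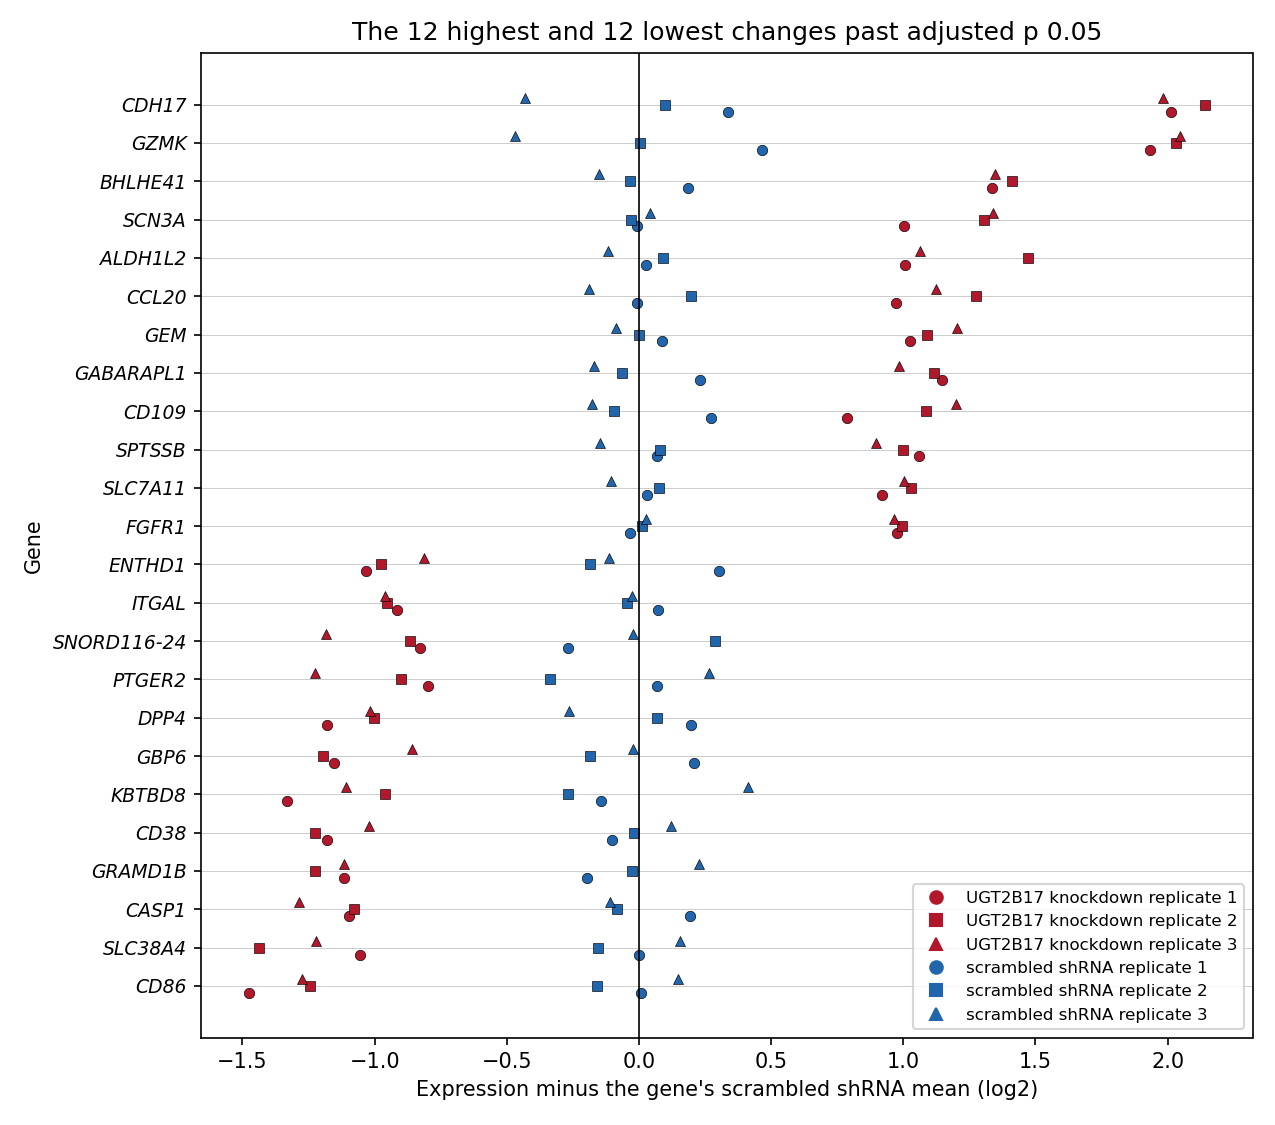
Expression of each gene on each array minus that gene's scrambled mean (horizontal axis, log2) for the 12 strongest increases and 12 strongest decreases (vertical axis), with 1 symbol per array. In all 24 genes the 3 knockdown arrays lie on one side of the 3 scrambled arrays, with CDH17 and GZMK near 2.04 and 2.01.

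Of 33 gene lists, camera with a preset correlation called 9, of which 5 were higher and 4 lower in the knockdown. None of the 9 calls held when the correlation between genes was estimated from the arrays: 0 of 33 lists passed that test, and 2 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list moves on balance one way without comparing it with other genes, called 2 lists: ER stress and amino acid response, and plasma cell differentiation. Without scrambled replicate 3, camera called 4 lists, all among the 9. Each SE of a list mean is over members and treats the genes as independent. The estimated correlation between members was 0.885 for MYC targets, 0.65 for histones, 0.517 for oxidative phosphorylation and 0.507 for DNA replication. The SEs of these list means therefore understate the uncertainty between arrays.

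The ER stress and amino acid response list was higher in camera, with 39 of 45 members above 0. Of 45 measured members, 11 rose, 0 fell and 34 did not pass over all genes; adjusted over the list alone, 26 rose. SLC7A11 rose by 0.98 log2 units, CTH, a cysteine-forming enzyme, by 0.85 ± 0.09 (SE), ASNS, asparagine synthetase, by 0.62 ± 0.08, and CHAC1, which degrades glutathione, by 0.64 ± 0.09. The list's mean log2 fold change was 0.26 ± 0.04 (SE over members; camera adjusted p = 7.59e-15). The adjusted p was 0.214 with an estimated correlation and 0.0179 by fry. The mean was 0.28 without scrambled replicate 3.

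Replication-dependent histone genes were lower as a list. Of 39 measured members, 4 fell, 0 rose and 35 did not pass over all genes; adjusted over the list alone, 20 fell. The 4 were H2BC12 at −0.92 ± 0.07, H4C8 at −0.53 ± 0.10, H2BC21 at −0.53 ± 0.12 and H2BC11 at −0.44 ± 0.10 log2 units (SE). The list's mean was −0.34 ± 0.03 (camera adjusted p = 1.45e-14), and the adjusted p was 0.730 with an estimated correlation. The mean was −0.21 without scrambled replicate 3, where the call held. Histone genes are near-identical copies, so their probe sets may share signal and single members are uncertain.

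Lists of growth and energy metabolism, 3 in number, were lower in camera, with almost no single gene passing. MYC targets and ribosome biogenesis had a mean of −0.21 ± 0.02 log2 units (SE over members) for 36 members (camera adjusted p = 0.000145). Of these members, 0 passed over all genes or adjusted over the list alone. WDR74 read −0.34, DKC1 −0.35 and NHP2 −0.28, and MYC itself 0.18, none of which passed. Oxidative phosphorylation had a mean of −0.12 ± 0.02 over 64 members, of which 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.000117); NDUFB8 read −0.39 and ATP5MC2 0.27, which did not pass. DNA replication had a mean of −0.11 ± 0.02 over 49 members (camera adjusted p = 0.000756), of which RRM2, a subunit of ribonucleotide reductase, rose by 0.40 ± 0.08 and 48 did not pass; adjusted over the list alone, 1 rose. The adjusted p was 0.882 for each of the 3 lists with an estimated correlation. Without scrambled replicate 3, which stood above all other arrays on these lists, the means were −0.04, −0.04 and −0.03, and none of the 3 lists was called.

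Immediate early genes, which respond quickly to signals, were higher as a list. Of 36 measured members, 4 rose, 1 fell and 31 did not pass over all genes; adjusted over the list alone, 12 rose and 2 fell. DUSP4, a MAP kinase phosphatase, rose by 0.81 ± 0.10 log2 units (SE), NR4A3, an orphan nuclear receptor, by 0.47 ± 0.07 and KLF10, a zinc finger transcription factor, by 0.39 ± 0.08, while IER3 fell by 0.33 ± 0.06. The mean was 0.14 ± 0.04 (camera adjusted p = 1.86e-05), and the adjusted p was 0.665 with an estimated correlation.

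B cell identity genes were also higher as a list in camera (mean 0.11 ± 0.05 log2 units over 30 members; adjusted p = 0.00636), with an adjusted p of 0.730 with an estimated correlation. TCL1A, an AKT coactivator, rose by 0.62 ± 0.08 and CD24, a surface glycoprotein, by 0.66 ± 0.10, while FCRL3, an Fc receptor-like protein, fell by 0.59 ± 0.11 and 27 did not pass; adjusted over the list alone, 8 rose and 4 fell. In the glycolysis and hypoxia list (mean 0.10 ± 0.03 over 37 members; adjusted p = 0.0139), SLC2A3, a glucose transporter, rose by 0.63 ± 0.09, BHLHE40 by 0.46 ± 0.07 and HILPDA by 0.37 ± 0.07, and 34 did not pass; adjusted over the list alone, 4 rose and 1 fell. In the T and NK cell marker list (mean 0.12 ± 0.09 over 27 members; adjusted p = 0.0218), GZMK rose by 2.01 and GNLY, granulysin, by 0.55 ± 0.08, while KLRD1, an NK cell receptor subunit, fell by 0.64 ± 0.08 and 24 did not pass; adjusted over the list alone, 6 rose and 1 fell. The adjusted p was 0.730 for both lists with an estimated correlation. Neither was called without scrambled replicate 3, with means of 0.06 and 0.08, or with array weights, and the T and NK cell call was also lost without knockdown replicate 1 or 2 and after another quantile normalisation.

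**Figure D3:**
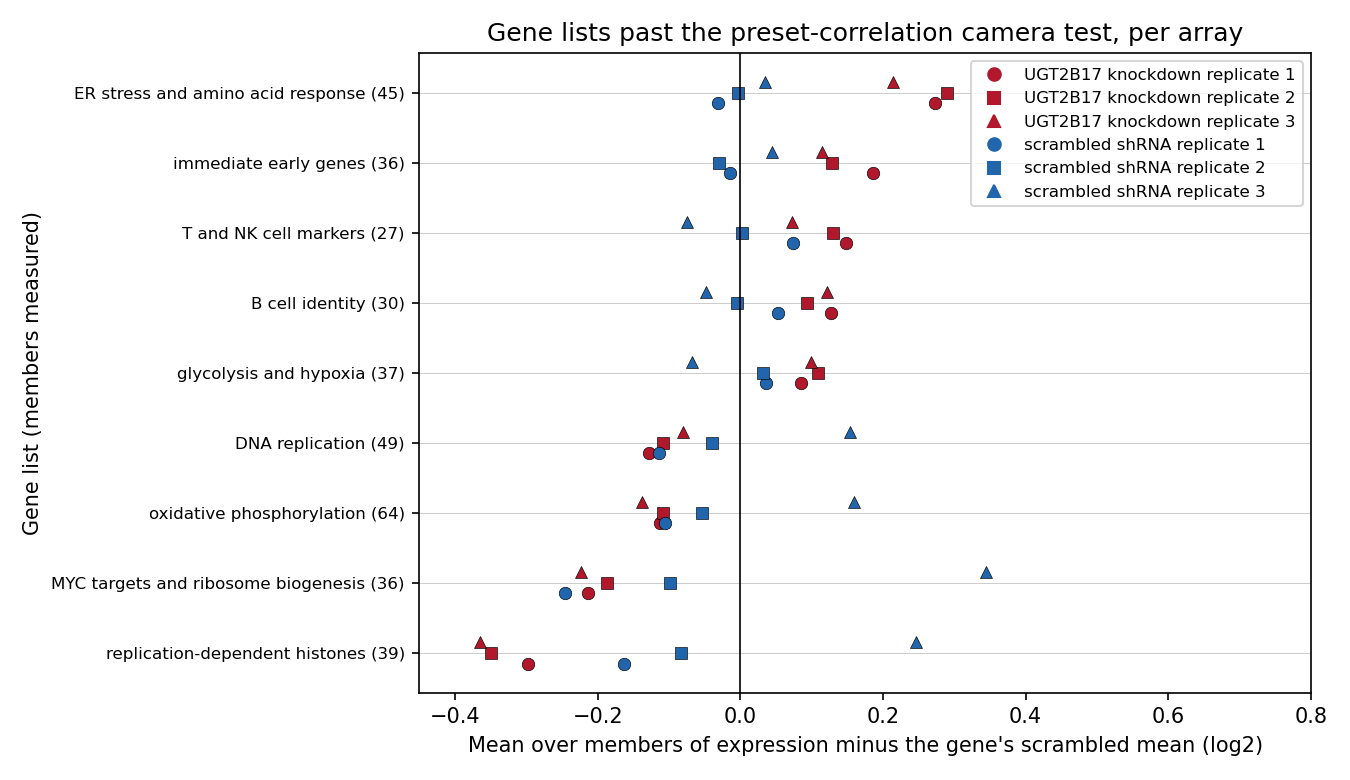
Mean over the members of each of the 9 called lists (vertical axis, members measured in brackets) of expression minus the gene's scrambled mean (horizontal axis, log2), with 1 symbol per array. On MYC targets and ribosome biogenesis, scrambled replicate 3 lies at 0.34 while scrambled replicate 1, at −0.25, lies below the knockdown arrays; on the ER stress and amino acid response the 3 knockdown arrays, from 0.21 to 0.29, lie above every scrambled array.

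Camera did not call the other 24 lists, and several held genes that changed in both directions. Fry's mixed test, which asks whether a list's genes change in either direction, called 25 of the 33 lists. It does not compare a list with other genes, and 3341 of 18404 genes had an unadjusted p under 0.05 in limma. Many lists would pass it on that ground, so the count does not set these lists apart. The apoptosis list passed too (fry mixed adjusted p = 0.000297), though none of its genes passed in limma. Of 52 interferon response genes, 3 rose and 6 fell over all genes, and 5 rose and 9 fell adjusted over the list alone: the antiviral synthetases OAS3 and OAS1 rose by 0.74 ± 0.09 and 0.54 ± 0.07 log2 units (SE), while IFI6 fell by 0.54 ± 0.07 and IFIT1 by 0.56 ± 0.09 (list mean −0.02; adjusted p = 0.427). Of 44 adhesion and migration genes, 3 rose and 5 fell, and 6 rose and 10 fell adjusted over the list alone: LGALS3, galectin-3, rose by 0.62 ± 0.08, while CD44, a hyaluronan receptor, fell by 0.48 ± 0.07 and VCL, vinculin, by 0.46 ± 0.08, besides ITGAL (list mean −0.06; adjusted p = 0.256). Of 32 CLL-associated genes, 2 rose and 3 fell, and 3 rose and 6 fell adjusted over the list alone: CLNK, an adaptor of immunoreceptor signalling, rose by 0.84 ± 0.07 and TCL1A by 0.62, while CD38 fell by 1.14 and CD200 by 0.39 ± 0.07 (adjusted p = 0.782). Of 18 plasma cell differentiation genes, 2 rose and 3 fell, and 5 rose and 4 fell adjusted over the list alone: MZB1, a chaperone of antibody-secreting cells, rose by 0.44 ± 0.08, while TNFRSF17, the receptor BCMA, fell by 0.66 ± 0.07 and ELL2, a transcription elongation factor, by 0.51 ± 0.06, besides CD38 (camera adjusted p = 0.972; fry adjusted p = 0.0415).

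Of 33 NF-kappaB targets, 3 rose and 3 fell, and 6 rose and 6 fell adjusted over the list alone: RGS1, a regulator of G protein signalling, rose by 0.89 ± 0.08 log2 units (SE), CCL22, a chemokine, by 0.58 ± 0.09 and TNIP1 by 0.47 ± 0.06, while CD83 fell by 0.39 ± 0.07 (adjusted p = 0.928). Of 54 cytokines, chemokines and their receptors, 5 rose and 2 fell, and 9 rose and 4 fell adjusted over the list alone, with TNFRSF1B at 0.43 ± 0.07, TNFRSF14 at 0.41 ± 0.07 and IL32 at 0.39 ± 0.07 besides CCL22 (adjusted p = 0.782). Of 37 B cell receptor signalling genes, PRKCB, a protein kinase C, fell by 0.35 ± 0.07 and 36 did not pass, and 2 rose and 3 fell adjusted over the list alone (mean −0.05; adjusted p = 0.431). Of 27 p53 targets, CCNG1 rose by 0.52 ± 0.07 and FBXW7 by 0.38 ± 0.08 (adjusted p = 0.782), and the same 2 passed adjusted over the list alone. None of 33 apoptosis regulators passed either way in limma (mean −0.03; adjusted p = 0.542). The mean, median and camera direction differed in sign for the cytokine, CLL-associated, p53, NF-kappaB, plasma cell and epithelial lists.

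Among the drug, hormone and lipid lists, 4 of 58 other drug metabolism and conjugation genes rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone (mean 0.05; adjusted p = 0.256). They were GSTA4, a glutathione transferase, at 0.98 ± 0.09 log2 units (SE), ABCB1, the multidrug transporter, at 0.56 ± 0.07, AHR, the aryl hydrocarbon receptor, at 0.39 ± 0.06, and MGST3 at 0.34 ± 0.07. Of 30 genes of steroid hormone metabolism and receptors, SRD5A1, a steroid 5-alpha-reductase that makes dihydrotestosterone, fell by 0.33 ± 0.06 and 29 did not pass, and 1 rose and 1 fell adjusted over the list alone (mean 0.01; adjusted p = 0.550). Of 36 androgen response genes, PLPP1 rose by 0.41 ± 0.09, ELL2 fell by 0.51 and 34 did not pass, and 1 rose and 2 fell adjusted over the list alone (mean −0.02; adjusted p = 0.782). In fatty acid synthesis, ELOVL7, a fatty acid elongase, fell by 0.78 ± 0.11 and 17 of 18 did not pass over all genes; 1 fell adjusted over the list alone (mean −0.13; adjusted p = 0.0606), and the list was called without scrambled replicate 1, with array weights and with the replicate block. None of 20 cholesterol synthesis genes passed either way (mean 0.05; adjusted p = 0.176).

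In the remaining lists few genes passed. Of 23 NRF2 targets, SLC7A11 rose by 0.98 log2 units and KEAP1 fell by 0.38 ± 0.08 (SE), and 4 rose and 3 fell adjusted over the list alone (mean 0.02; adjusted p = 0.550). Of 24 genes of nucleoside analogue handling, TK2 rose by 0.46 ± 0.08 and RRM2 by 0.40, and 3 rose and 5 fell adjusted over the list alone (mean −0.04; adjusted p = 0.890). Of 15 genes of MHC class II presentation, HLA-DQB1 rose by 0.57 ± 0.09, and 2 rose adjusted over the list alone (mean 0.05; adjusted p = 0.427). None of 44 G2/M cell cycle genes (mean −0.05; adjusted p = 0.0602), 57 ribosomal protein genes (mean −0.01; adjusted p = 0.928) or 21 heat shock genes (mean −0.09; adjusted p = 0.427) passed over all genes or adjusted over the list alone. The G2/M list was called without knockdown replicate 3, without scrambled replicate 2 and with an intensity trend, and the heat shock list without scrambled replicate 1. Among markers of other cell types, 0 of 21 monocyte and granulocyte markers (mean −0.04; adjusted p = 0.620) and 0 of 11 erythroid and platelet markers (mean 0.03; adjusted p = 0.696) passed either way. Of 25 epithelial and fibroblast markers (mean −0.03; adjusted p = 0.928), KRT18 rose by 0.32 ± 0.07 while FN1 fell by 0.63 ± 0.14, FBN1 by 0.59 ± 0.07 and SPARC by 0.32 ± 0.07, and the same numbers, 1 and 3, passed adjusted over the list alone. The rise of KRT18 rests on its brighter probe set, and the dimmer one read 0.13 (limma over all deposited probe sets, unadjusted p = 0.352). Which of these probe sets reads KRT18 itself was not tested, so its rise is uncertain.

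The means of several lists that camera did not call moved when scrambled replicate 3 was left out, and camera again called none of these lists. Without it 4 means turned sign, to 0.02 log2 units for heat shock, 0.01 for nucleoside analogue handling, 0.01 for p53 targets and −0.01 for steroid hormone genes. Means that moved further from 0 by over 1.5 times became 0.07 for NRF2 targets, 0.06 for NF-kappaB targets, 0.04 for cytokines, chemokines and their receptors, −0.07 for monocyte and granulocyte markers and −0.06 for epithelial and fibroblast markers. Means that moved closer to 0 by over 1.5 times became −0.02 for B cell receptor signalling, −0.03 for G2/M, 0.01 for erythroid and platelet markers and −0.01 for ribosomal proteins.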

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

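UGT2B17 was lower and past the threshold in every alternative that gave a value, with log2 fold changes from −0.50 with array weights to −0.71 without scrambled replicate 2 and adjusted p from 0.00102 to 0.0407; with only the brighter genes it had no value. The 665 changed genes (354 higher, 311 lower) became 3511 (1802, 1709) with array weights, 165 (86, 79) probe sets with all deposited probe sets tested, 1207 (612, 595) at an adjusted p under 0.1, and 17 (9, 8) at a log2 fold change of at least 1. Leaving out 1 array gave 152 to 759 genes, 75 to 391 higher and 77 to 368 lower, and 4 to 11 gene lists. The 9 called lists became 0 with an estimated correlation and 2 by fry, 1 of them among the 9. With the replicate block, 367 genes (189 higher, 178 lower) passed, 357 of them among the 665, which has fewer residual degrees of freedom. Same-numbered arrays did not deviate together (r −0.08, −0.01 and −0.08), and 0 of 3 knockdown arrays correlated best with their own number, so the numbers share no known pairing. The other alternatives gave 591 to 821 genes. The cause of the array weight count was not tested; it gave scrambled replicate 2 a weight of 6.12 and scrambled replicate 3 a weight of 0.2496. For the 24 strongest genes, 341 of 349 alternatives kept direction and call, and 8 lost the call. For 56 further list members that passed, 622 of 827 kept both and 205 lost the call. For the lists, 424 of 459 kept both, 27 lost a call and 8 gained one; no called gene or list reversed, and uncalled lists turned direction, uncalled, in 24 cases. Signal near background limits UGT2B17 and other dim probe sets.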

Other observations

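The genes in this paragraph lie outside the naming rule and were chosen after their values were seen. CCND2, cyclin D2, fell by 0.85 ± 0.14 log2 units (SE; limma adjusted p = 0.0153), CRLF2, a cytokine receptor subunit, by 0.85 ± 0.12 (adjusted p = 0.00955) and ICOS, a costimulatory receptor on a dim probe set, by 0.68 ± 0.07 (adjusted p = 0.00217). SERPINA9, a serpin of germinal centre B cells, rose by 0.95 ± 0.12 (adjusted p = 0.00654). Of 10 HOXB transcription factor genes, HOXB9 rose by 0.90 ± 0.10, HOXB3 by 0.46 ± 0.09 and HOXB7 by 0.36 ± 0.07, and 3 of the 10 were higher past the threshold under both scalings too. Of 6 guanylate-binding protein genes, GBP6 fell by 1.07 ± 0.12 and GBP4 by 0.75 ± 0.07, and 2 of the 6 passed under both scalings too, while the other 4 read from −0.17 for GBP5 to −0.03 for GBP2 and did not pass.

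Of 20 SNORD116 small nucleolar RNA genes, also looked at after SNORD116-24 was seen, 6 fell and 14 did not pass, with a mean of −0.45 ± 0.07 log2 units (SE over genes) that was −0.46 without scrambled replicate 3 and −0.45 and −0.47 under the 2 scalings. The 20 SNORD115 genes had a mean of −0.02 ± 0.02 and 0 passed, and 66 other SNORD genes had a mean of −0.12 ± 0.02. Whether SNORD115 is expressed in these cells was not tested, so its values are no control for SNORD116. SNORD116 copies are near-identical, so the 20 values are not independent.

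Other splits of the 6 arrays into 3 and 3 were tested in all 10 ways, too few for a share under 0.05. The real split called 665 genes, and 1 of the 10 splits, the real one, called as many, the highest other count being 0. For gene lists the real split called 9 and the highest other split 11, so 2 of the 10 splits called as many. Camera with its preset correlation therefore called lists on splits that mix the groups. Such splits are not free of a knockdown effect: part of it stays between their groups, and part widens the spread within them. Their gene and list counts are thus no clean reference for chance.

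The tests below were planned before their results were seen, except the values without scrambled replicate 3 for gene families, synthetases and neighbouring pairs, and the bounds that sorted the synthetase and 20-gene window outcomes, which were chosen after those results were seen. The higher level of the ER stress and amino acid response list did not rest on scrambled replicate 3: without it the mean over 45 members was 0.276 ± 0.035 log2 units (SE), against 0.259 with all arrays. General folding stress of the ER stays open, since 14 chaperone and quality-control members had a mean of 0.189 ± 0.047, above the bound of 50% of the mean of the other 31, 0.291 ± 0.047 (permutation p over genes 0.196 for the difference of 0.102). A response to UGT2B17 loss, an effect of the hairpin on other transcripts, and a difference in medium use between cultures may each lie behind it, and the design, whose labels do not give the number of targeting constructs, separates none of them. With all arrays, the aminoacyl-tRNA synthetases outside the list gave a negative result. The mean of 15 cytosolic genes minus that of 16 mitochondrial ones was −0.0399 log2 units (permutation p over genes 0.601). The cytosolic mean of −0.10 ± 0.06, or 0.01 ± 0.05 without scrambled replicate 3, lay below the mean of the other members. Without that array 2 of 15 cytosolic and 0 of 16 mitochondrial genes were called higher, against 0 and 0 with all arrays. Synthetases held in the list were not part of this test. Of these, CARS1 rose by 0.48, while AARS1 at 0.24, GARS1 at 0.26 and WARS1 at −0.14 did not pass.

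The lower level of the MYC, DNA replication and oxidative phosphorylation lists is a candidate artifact of 1 array. Over their 149 members the mean was −0.137 ± 0.011 log2 units (SE over members) with all arrays. It was −0.0356 ± 0.0090 without scrambled replicate 3, a drop to under 50% that was set as the bound in advance. These SEs treat correlated genes as independent and understate the uncertainty. A trend with brightness alone is argued against only as the source of the mean with all arrays. Of 10000 random lists matched on mean level, 0 were as low. Their median was −0.0217, with 95% between −0.052 and 0.0093. Random genes were drawn independently while the members move together, so this range is too narrow and the count of 0 overstates the contrast. The smaller mean without scrambled replicate 3 was not tested against matched lists, so brightness stays open for it. Whether that array differs through RNA handling or through the growth state of its cells was not tested.

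T or NK cells among the knockdown cells are argued against only as the source of the rise of GZMK. For the T and NK cell marker call they stay open. The bound was set on GZMK, and the pan T and NK markers moved no less than the list, whose median was 0.0498 log2 units. The median over 16 pan T and NK markers was 0.0875 log2 units (quartiles 0.022 and 0.21), far below 50% of the rise of GZMK, 2.01, and CD3D, CD3E and CD3G, on dim probe sets with mean levels of 5.08, 4.99 and 5.21, read 0.05, 0.02 and 0.04. Of the 16, 13 were above 0: GNLY rose by 0.55, NKG7, PRF1 and LCK read 0.25, 0.17 and 0.23 and did not pass, and KLRD1, also on a dim probe set, fell by 0.64. The list mean of 0.117 with all arrays lay above the list median of 0.0498, and GZMK, 1 of 27 members, raises it. Part of the list mean may also come from scrambled replicate 3, since it was 0.0794 ± 0.085 without that array, which leaves this open. A change of GZMK within the MEC-1 cells remains a hypothesis.

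Changed genes lay next to each other on chromosomes more often than in shuffled orders. Among 18107 genes in RefSeq order, without small nucleolar RNA and histone genes, 37 neighbouring pairs changed in one direction, against a median of 12 and an upper limit of 19 for the central 95% of 10000 shuffles (permutation p = 0.0001, the smallest they can give). Without scrambled replicate 3, where 739 instead of 652 of these genes were called, 40 pairs did so, against a shuffled median of 15 and an upper limit of 23 (permutation p = 0.0001). Pairs that changed in opposite directions numbered 10, against a shuffled median of 12. Examples are CDH17 with GEM, CD86 with ILDR1, RGS1 with RGS13 and RGS2, and OAS1 with OAS3; some pairs are related genes that could share probe signal or regulators. A copy-number difference between the cultures is not settled: the highest mean over 20 neighbouring genes was 0.182 log2 units, between the median of 0.165 and the 95th percentile of 0.201 of shuffled orders (permutation p = 0.195). The bound written in advance took any such p as evidence against it, and was set aside because a missed threshold excludes nothing and shorter segments would escape a 20-gene window. Shared local regulation may contribute to the 37 pairs and was not tested further.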
